A study of Mus musculus with 24 samples.

How the data were processed

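The data are 24 real-time PCR arrays of microRNAs (miRNAs) from mouse muscle stem cells, the resident stem cells of skeletal muscle. Per the labels, the cells came from male C57BL/6 mice, RNA was extracted with Trizol, and TaqMan rodent microRNA cards were run for 40 cycles on an ABI 7900HT instrument. Quiescent cells form the 0 h group, and activated cells form groups at 36, 60 and 72 h after muscle injury. Every group has 3 replicates, each measured on a card of type A and a card of type B. The labels do not give the card type of an array, which was read from the assay names in its own file. The series' design text calls the replicates technical, so the p-values measure technical spread only and do not cover variation between mice. The labels name no cell sort.

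Per the file headers, each array's file holds a threshold cycle (Ct) per spot. A Ct is the PCR cycle at which the signal crosses a threshold, so it is an inverse log2 scale, and spots without a Ct are empty. The authors also deposited 1 table per card with Ct, dCt and fold change against day 0. In these tables the Ct of the 0, 36 and 60 h arrays matched the single-array files within 0.001, with 40 written where no Ct was determined. Per the file headers, the last time point of these tables is day 3.5, whereas the labels give 72 h. The labels were followed, and 48 other per-sample columns, including those of day 3.5, were not used. The deposited fold changes are linear ratios, made by the authors from dCt and averaged over 3 replicates. The software and threshold that gave the Ct values are not given in the sources used here.

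The level of an assay on an array was the mean Ct of the 4 MammU6 (U6 small nuclear RNA) spots of that array minus the Ct of the assay, a log2 scale on which higher values mean more RNA. U6 was chosen because the deposited dCt equals Ct minus a constant that differed by at most 0.001 from the mean U6 Ct of the group, except on card B at 36 h. There the constant was 16.97 and the mean U6 Ct 14.7. U6 was taken per array here, not per group. Card A holds 375 miRNA assays, each in 1 spot. Card B holds 209 assays, 59 in 1 spot and 150 in more spots, whose Ct values were averaged. Of the 584 assays, 517 are named for mouse and 67 for rat, and assays of both species for the same miRNA were counted separately. The control RNAs MammU6, snoRNA135, snoRNA202, snoRNA429, U87 and Y1 and the plant miRNA ath-miR159a were not counted as miRNA assays.

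An assay was detected on an array if all its spots had a Ct below 35. Undetected values were left out. A comparison was tested for an assay with at least 2 detected replicates in each group. An assay detected in 3 replicates of a group and at most 1 of the other was not tested. It was counted as detected in that group alone, even if 1 replicate or some spots of the other group had a Ct. Where no spot of the other group had a Ct below 35, its fold is given as a bound (at least) with that group set to Ct 35. Where some spots did, the fold is given against the highest single spot of that group, a way chosen after seeing the data. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes), in 1 fit per card over its 12 arrays. P-values were adjusted by the Benjamini-Hochberg method over the assays of both cards. An assay was called changed at an adjusted p below 0.05 and at least a 2-fold change. Errors given as ± are standard errors of the log2 change from these fits, with n = 3 arrays per group. The comparisons were each later group against 0 h, the 3 later groups against each other, and the mean of the 3 later groups against 0 h.

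Gene lists and the rule for named assays were fixed before the data were examined. Named are the 8 largest increases and decreases against 0 h (5 between later groups) among called assays detected in 3 of 3 replicates of both groups, with no overlap between the replicates. For 3 against 3 replicates chance gives no overlap in 10% of cases (not computed from these data). Also named are the 5 largest differences each way among assays detected in 1 group alone, ranked with undetected values at Ct 35, the 2 to 4 largest changes as examples of a list, and miR-489, miR-206, miR-1, miR-133a, miR-133b, miR-31, miR-27b, miR-16, miR-126-3p, miR-223, miR-451 and miR-21 in every comparison that measured them. The 23 lists covered muscle-enriched miRNAs, the miR-489 and miR-653 locus, reported regulators of muscle stem cells, miRNA families and clusters, and miRNAs enriched in other cell types. Strands marked with an asterisk were left out of lists. The miR-489 locus was the subject of the published work on these samples, so its list is not independent evidence. Each list with at least 3 assays was tested against the other assays with camera (limma) on 330 assays, with undetected values at Ct 35, a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over 99 tests. The tests were repeated with an estimated correlation. Assays of both cards were pooled in them, each card on its own U6. A difference between the cards can therefore enter the shift of a list. Mouse and rat assays of 1 miRNA, as for miR-489 and miR-1, entered a list as separate members.

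The limma step was tested on simulated data in which sets of 15 assays were changed by a known amount, in 20 sets per comparison. For 36 h against 0 h (272 assays), 90.3% of assays changed by log2 1.5 were called, 99.7% of those changed by log2 3, and 0.189% of unchanged assays. For 72 h against 60 h (265 assays), 92% of assays changed by log2 1.5 were called and 0.195% of unchanged assays. For 60 h against 0 h, camera found a list of 29 assays shifted by log2 -1 in 100% of 100 simulated sets, and 2.8% of 500 random lists passed an unadjusted p of 0.05. The simulated assays varied independently of each other. The 2.8% therefore does not apply to lists whose assays vary together, as clusters and families may.

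Precision followed the Ct. The median SD between the 3 replicates was 0.067 cycles below Ct 25, 0.156 between Ct 25 and 30, and 0.497 between Ct 30 and 35. The number of arrays limits the precision further. Replicates of a group held no identical Ct values. The plant control had no Ct in any of the 23 spots present, and 1 array lacked that spot.

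Alternatives fixed beforehand were snoRNA135, snoRNA202 or the mean of the assays detected on 12 of 12 arrays as normalizer, detection limits of Ct 32 and 40, undetected values set to Ct 35, 3 detected replicates in both groups, a variance trend, a fit on the compared groups alone, a replicate block, no minimum fold, adjustment within each card, each replicate left out in turn, and the deposited fold changes. Chosen after seeing the data were the constants of the deposited tables, detection by any spot of an assay, and fits without the 36 h arrays. Names of neighbouring genes came from a RefSeq table of assembly GRCm38.p6. No genome positions are given, since the assays name mature miRNAs. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.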

Results

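The series profiled miRNAs in muscle stem cells before and during activation. Muscle stem cells lie quiescent along the muscle fibre and enter the cell cycle after injury. Quiescent cells (0 h) and cells 36, 60 and 72 h after injury were each measured on 3 arrays of both card types, 24 arrays in total. Of 584 assays, 222 were detected on 12 of 12 arrays of their card and 219 on none. The assays detected in 3 of 3 replicates numbered 259 at 0 h, 314 at 36 h, 271 at 60 h and 264 at 72 h. Per array, 181 to 212 assays were detected on card A and 89 to 120 on card B. The arrays give Ct values and no read depth.

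All levels below are relative to U6 RNA, and the other control RNAs did not hold a constant ratio to it. On card A, snoRNA202 fell by 0.88 at 36 h, by 2.40 at 60 h and by 3.05 at 72 h against 0 h (log2). snoRNA135 fell by 0.22, 0.34 and 0.87, while the log2 change of Y1 was 0.65, 0.11 and -0.32. The cards differed at 72 h: on card B the change was -0.35 for snoRNA135, -2.61 for snoRNA202 and 0.72 for Y1, and the median assay was at -0.28, against -1.37 on card A. The median change of the tested assays was 0.82 at 36 h, -0.37 at 60 h and -0.77 at 72 h with U6. It was 1.74, 2.08 and 2.04 with snoRNA202, and 1.05 at 36 h and -0.17 at 72 h with snoRNA135. It was -0.36, -0.30 and -0.10 with the mean of the assays detected on 12 arrays (the global mean). The direction of a moderate change therefore needs the normalizer beside it. Changes relative to the median of all tested assays, pooled over both cards, are given for the leading miRNAs.

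**Figure D1:**
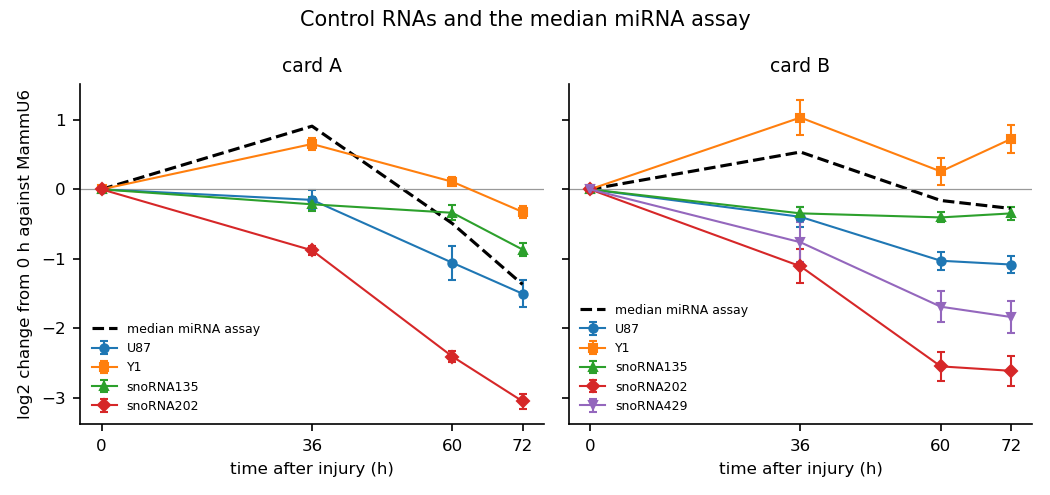
Log2 change from 0 h (vertical axis) of each control RNA against U6 at 0, 36, 60 and 72 h (horizontal axis) on card A and card B, with bars for the SD (the root of the summed squares of both groups' SD, n = 3 arrays per group) and the median miRNA assay as a dashed line. snoRNA202 lies lowest at each later time on both cards, at -3.05 on card A at 72 h, and the median assay on card A goes from 0.91 at 36 h to -1.37 at 72 h.

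The comparison of 36 h with 0 h asked which miRNAs differ between quiescent cells and cells early after injury. The increases were led by miR-142-3p and miR-223, known as miRNAs of blood-derived cells, and by miR-31, which is reported to repress the mRNA of the myogenic factor Myf5. miR-142-3p was 373-fold higher (log2 8.54 ± 0.59), miR-223 200-fold (7.65 ± 0.07) and miR-31 156-fold (7.29 ± 0.09). miR-142-3p was near the detection limit at 0 h (mean Ct 33.6, SD 1.54 over 3 arrays), and leaving out 1 of the 0 h arrays gave 8.02 to 9.43, above miR-223 each time. The same 0 h arrays enter its later folds, and for miR-182 leaving out 1 of them gave 5.28 to 6.37. miR-322 rose 99.5-fold, miR-21 98.2-fold, miR-182 61.4-fold, miR-146b 33.1-fold and miR-221, a reported repressor of the cell cycle inhibitor p27, 30.4-fold. The decreases were led by miR-433, which was 20.7-fold lower (log2 -4.37 ± 0.12), followed by miR-485* (6.71-fold), miR-329 (4.86-fold), miR-543 (4.13-fold), miR-702 (4.13-fold), miR-127 (3.87-fold), miR-411* (3.73-fold) and miR-667 (3.58-fold). Of these 8 decreases, 7 come from hairpins of the imprinted Dlk1-Dio3 locus, and miR-702 does not. miR-489, whose gene lies within Calcr, fell 2.64-fold on the mouse assay (log2 -1.40 ± 0.16, adjusted p = 2.39e-05) and 2.54-fold on the rat assay (-1.35 ± 0.22, adjusted p = 0.000214). Against the median assay, the log2 change was 6.47 for miR-31, -2.22 for miR-489 on the mouse assay and -2.77 for miR-127. With snoRNA202 as normalizer the calls of miR-489 (log2 -0.52 mouse, -0.24 rat), miR-329 (-1.40), miR-702 (-0.94), miR-411* (-0.79) and miR-667 (-0.96) were lost, and that of miR-329 was also lost with a detection limit of Ct 40 (-2.28).

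In all, 153 of 272 tested assays changed at 36 h, 120 higher and 33 lower. The split was 180 and 6 with snoRNA202 and 59 and 89 with the global mean. A further 45 assays were detected at 36 h alone and 4 at 0 h alone. Of the 45, 11 had some 0 h spot with a Ct below 35, and 2 of the 4 had such a spot at 36 h. Those at 36 h included miR-374 (at least 2364-fold higher), miR-31* (at least 532-fold), let-7f (at least 325-fold) and miR-15a (at least 228-fold), and miR-18a, 383-fold above its highest 0 h spot. Those at 0 h were miR-302a (at least 4.80-fold lower at 36 h) and miR-363 (at least 4.42-fold), and against their highest spot at 36 h rno-miR-379* (6.82-fold) and miR-501-3p (3.38-fold).

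Members of the miR-17-92 cluster and its paralogs, which promote cell division in many tissues, were higher at 36 h for 9 of 11 tested assays, with 9 also when adjusted over the list alone and 11 with snoRNA202. Of the list, miR-18a was detected at 36 h alone, and miR-363 went the other way and was detected at 0 h alone. miR-20b rose 29.5-fold, miR-19a 29.2-fold, miR-20a 27.6-fold and miR-17 19.4-fold, and the log2 changes of miR-25 (0.85 ± 0.09) and miR-92a (0.76 ± 0.07) were below the minimum fold. Both were called with snoRNA202 (1.72 and 1.64), miR-25 also with snoRNA135 (1.06), and both were below 0 with the global mean (-0.44 and -0.53). The list passed camera (adjusted p = 0.00842) but not with an estimated correlation (adjusted p = 0.316). Of 5 tested muscle-enriched assays, 4 were higher, again 4 when adjusted over the list alone, against 5 with snoRNA202 and 2 with the global mean. miR-133b rose 15.6-fold, miR-1 7.85-fold on the mouse assay and 4.56-fold on the rat assay, and miR-133a 3.79-fold, while miR-206 had a log2 change of 0.48 ± 0.12, with 1.59, a call, with snoRNA202 and -0.29 with the global mean. Camera gave an adjusted p of 0.130 for this list, and 0.321 with an estimated correlation. With the global mean the calls of miR-133a (log2 0.63) and the rat assay of miR-1 (0.90) were lost. miR-27b had a log2 change of 0.32 ± 0.10 (1.20, a call, with snoRNA202 and -0.97 with the global mean), and miR-16 rose 2.57-fold, a call lost with the global mean (log2 0.07).

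The Dlk1-Dio3 list, a large imprinted cluster of miRNA genes, had 12 of 29 tested assays lower and 0 higher at 36 h, with 12 changed when adjusted over the list alone. The list shifted down in camera (adjusted p = 6.36e-08) and kept this with an estimated correlation (adjusted p = 0.0318). The lower assays numbered 27 with the global mean, while 4 were lower and 4 higher with snoRNA202. Of the 3 assays of the miR-489 and miR-653 list, 2 were lower (2 over the list alone, 0 with snoRNA202 and 3 with the global mean), and miR-653 had a log2 change of -0.67 ± 0.27 that did not pass (0.44 with snoRNA202, and -1.45, a call, with the global mean). Camera gave an adjusted p of 0.0399 for this list, lost with an estimated correlation (adjusted p = 0.201). The 2 lower assays of the list were the mouse and rat assays of miR-489, 1 miRNA that camera counted as separate members. This list was chosen on these samples and is not independent evidence of its direction.

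Some miRNAs enriched in other cell types were called higher at 36 h, but no list of them that could be tested passed camera. Of 5 tested leukocyte-enriched assays, 4 were higher: miR-142-3p, miR-223, miR-146a (9.57-fold) and miR-155 (4.05-fold, a call lost with the global mean, log2 0.73). The remaining assay, miR-150, had a log2 change of 0.41 ± 0.08, with 1.29, a call, with snoRNA202 and -0.88 with the global mean. With snoRNA202 5 were higher and with the global mean 3. The leukocyte list did not pass camera (adjusted p = 0.0856, and 0.316 with an estimated correlation). Both strands of the endothelial miR-126, whose gene lies within Egfl7, were higher, miR-126-3p 4.67-fold and miR-126-5p 3.87-fold, though neither was called with the global mean (log2 0.93 and 0.66). Of 4 tested assays of the mesenchymal and smooth muscle list, miR-199a-3p (9.16-fold), miR-143 (5.95-fold) and miR-214 (2.65-fold) were higher and miR-145 was not called (log2 -0.33 ± 0.06, and 0.55 with snoRNA202). With the global mean 2 were higher and 1 lower, with miR-214 at 0.12 and miR-145 at -1.62. This list did not pass camera (adjusted p = 0.476, and 0.623 with an estimated correlation). The erythroid miR-451 was detected at 36 h and not at 0 h, at least 64.8-fold higher. So were the epithelial miR-200c (at least 21.9-fold) and miR-205 (at least 5.13-fold), named after their values were seen, while the epithelial miR-203 was not called (log2 0.44 ± 0.08). miR-203 was at 1.32, a call, with snoRNA202 and at -0.85 with the global mean.

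**Figure D2:**
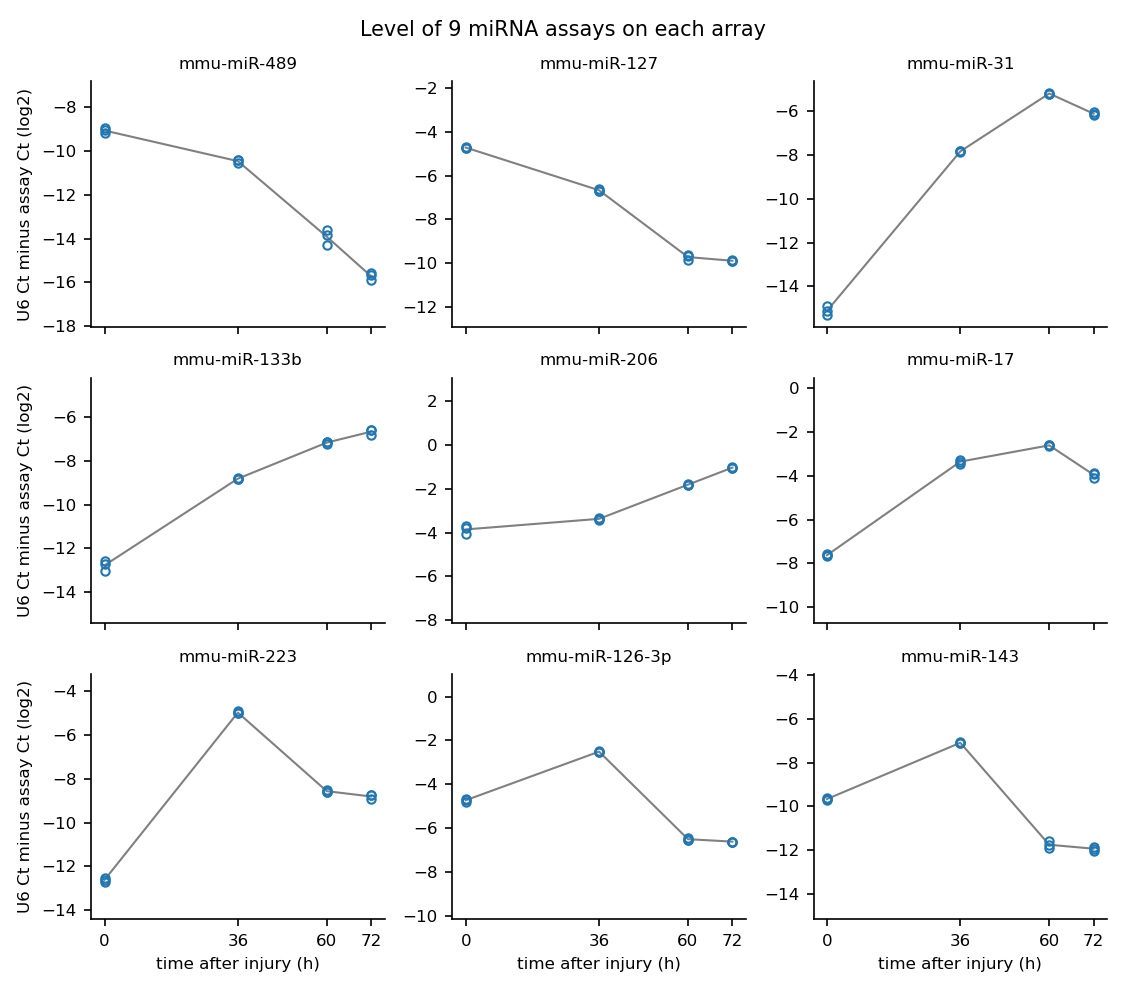
Level (U6 Ct minus assay Ct, log2, vertical axis, each panel spanning the same number of units) of 9 miRNA assays at 0, 36, 60 and 72 h after injury (horizontal axis), with 3 arrays per time as points and their mean as a line. With U6 as normalizer miR-489 and miR-127 lay lower at each later time than at 0 h, miR-31, miR-133b and miR-17 stayed above 0 h, and miR-223, miR-126-3p and miR-143 were highest at 36 h.

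The comparison of 60 h with 0 h extended this to a later stage. At 60 h, miR-31 was 979-fold above 0 h (log2 9.93 ± 0.09) and miR-182 413-fold (8.69 ± 0.45). miR-322 was 62.4-fold higher, miR-21 60.8-fold, miR-142-3p 60.2-fold, miR-19a 59.6-fold, miR-133b 48.8-fold and miR-221 46.0-fold. Among the decreases, miR-485* was 44.4-fold lower, miR-667 37.8-fold, miR-127 32.1-fold, miR-411* 28.5-fold, miR-495 25.6-fold and miR-434-3p 24.4-fold. miR-489 fell 28.9-fold on the mouse assay (log2 -4.85 ± 0.16, adjusted p = 9.55e-10) and 23.4-fold on the rat assay (-4.55 ± 0.22, adjusted p = 6.25e-09). Against the median assay the log2 change was 10.30 for miR-31 and -4.48 for miR-489. In total 161 of 250 tested assays changed, 70 higher and 91 lower, and the split was 179 and 20 with snoRNA202. A further 28 assays were detected at 60 h alone, including miR-374 (at least 3397-fold higher), miR-31* (at least 3261-fold), miR-15b* (at least 277-fold) and miR-20a* (at least 110-fold), and miR-18a, 1102-fold above its highest 0 h spot. The 23 detected at 0 h alone included miR-433 (at least 1318-fold lower at 60 h), miR-673-3p (at least 114-fold) and rno-miR-136* (at least 106-fold), and against their highest spot at 60 h miR-543 (61.6-fold) and miR-696 (3.07-fold). Some spot of the other group had a Ct below 35 for 8 of the 28 and 8 of the 23.

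By list, 19 of 22 tested Dlk1-Dio3 assays were lower at 60 h and 0 were higher, 19 also when adjusted over the list alone, and 7 more were detected at 0 h alone. With snoRNA202, 7 were lower and 3 higher. Camera gave an adjusted p of 2.73e-07 for this list, kept with an estimated correlation (adjusted p = 0.0318). The assays of the miR-489 and miR-653 list were lower for 3 of 3 (3 over the list alone), miR-653 by 15.1-fold, with a camera adjusted p of 0.1004 (0.311 with an estimated correlation). The miR-17-92 list was higher for 11 of 11 (11 over the list alone), miR-20a by 43.7-fold and miR-17 by 32.5-fold, while miR-363 was detected at 0 h alone, 1.97-fold above its highest 60 h spot. Its camera call (adjusted p = 2.92e-05) was lost with an estimated correlation (adjusted p = 0.187). The muscle-enriched assays were higher for 5 of 5 (5 over the list alone), including miR-133a (4.56-fold), miR-206 (4.13-fold, log2 2.05 ± 0.12) and miR-1 (3.25-fold on the mouse assay, 5.55-fold on the rat assay). Camera gave an adjusted p of 0.0182 for them, lost with an estimated correlation (adjusted p = 0.201).

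Leukocyte-enriched miRNAs differed among themselves at 60 h: miR-142-3p, miR-223 (16.6-fold) and miR-155 (3.77-fold) were higher, miR-146a was not called (log2 0.39 ± 0.09, and 2.79, a call, with snoRNA202) and miR-150 was 12.7-fold lower. With snoRNA202 4 were higher and 1 lower. Camera gave this list an adjusted p of 0.250 (0.447 with an estimated correlation). miR-126-3p was 3.43-fold lower than at 0 h (log2 -1.78 ± 0.05), but its log2 change was 0.63 with snoRNA202. In the mesenchymal and smooth muscle list 3 of 4 assays were lower, with miR-145 falling 18.7-fold and miR-143 4.25-fold, and with snoRNA202 1 was lower and 1 higher. Its camera adjusted p was 0.176 (0.407 with an estimated correlation). miR-451 was at least 5.08-fold higher at 60 h. miR-27b fell 2.19-fold, a direction that turned with snoRNA202 (log2 1.28), and miR-16 had a log2 change of 0.19 ± 0.06 (2.59, a call, with snoRNA202).

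At 72 h, miR-31 was 516-fold above 0 h (log2 9.01 ± 0.09), miR-133b 69.2-fold (6.11 ± 0.11), and miR-182 had a log2 change of 7.74 ± 0.45. miR-322 was 62.1-fold higher, miR-142-3p 48.7-fold, miR-21 22.5-fold, miR-19a 17.3-fold and miR-20b 15.5-fold. miR-489 was the most decreased assay by the naming rule, 101-fold lower on the mouse assay (log2 -6.67 ± 0.16, adjusted p = 5.75e-11) and 74.2-fold lower on the rat assay (-6.21 ± 0.22, adjusted p = 3.07e-10). miR-543 was 60.3-fold lower, miR-434-3p 38.6-fold, miR-127 36.1-fold, miR-224 34.5-fold, miR-676 33.8-fold and miR-667 33.6-fold. Against the median assay of both cards the log2 change was 9.78 for miR-31, -5.90 for miR-489 and -4.41 for miR-127. These assays are on card A, whose own median was -1.37, against -0.77 for both cards. Against the card A median the falls would be smaller and the rise of miR-31 larger. Of 244 tested assays 163 changed, 51 higher and 112 lower. The split was 65 and 85 with snoRNA135, 166 and 24 with snoRNA202, and 72 and 79 with the global mean. The 26 assays detected at 72 h alone included miR-31* (at least 2082-fold higher), miR-374 (at least 1102-fold) and miR-130b* (at least 72.2-fold), and against their highest 0 h spot miR-18a (368-fold) and rno-miR-351 (138-fold). The 28 detected at 0 h alone included miR-433 (at least 1596-fold lower), miR-696 (at least 133-fold) and miR-370 (at least 113-fold), and against their highest 72 h spot miR-382 (206-fold) and miR-10b (114-fold). For 6 of the 26 and 12 of the 28, some spot of the other group had a Ct below 35.

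All 22 tested Dlk1-Dio3 assays were lower at 72 h, 22 also when adjusted over the list alone, and 7 more were detected at 0 h alone. With snoRNA202 10 were lower and 0 higher. Camera gave an adjusted p of 6.51e-06, kept with an estimated correlation (adjusted p = 0.0352). Both cards were pooled in this test, with medians at 72 h of -1.37 on card A and -0.28 on card B. It was not run within each card, though the median of the list's tested assays (-3.90) was below both. Both tested assays of the miR-489 and miR-653 list were lower (2 over the list alone), and miR-653 was detected at 0 h alone, with its highest 72 h spot 32.7-fold lower. The muscle-enriched assays were higher for 5 of 5 (5 over the list alone), with miR-133a 9.17-fold, miR-206 7.09-fold (log2 2.83 ± 0.12), and miR-1 5.90-fold on the mouse assay and 7.01-fold on the rat assay above 0 h. Their camera call (adjusted p = 0.00128) was lost with an estimated correlation (adjusted p = 0.120). The miR-17-92 list was higher for 9 of 11 (9 over the list alone, 11 with snoRNA202), including miR-20a (14.8-fold) and miR-17 (12.8-fold), while miR-363 was detected at 0 h alone, at least 3.76-fold lower at 72 h. The log2 changes of miR-25 (-0.39 ± 0.09) and miR-92a (-0.30 ± 0.07) were not called with U6 and were 2.66 and 2.75 with snoRNA202 and 0.65 and 0.73 with the global mean. Its camera call (adjusted p = 0.000172) was lost with an estimated correlation (adjusted p = 0.208).

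miR-223 was still above 0 h at 72 h (log2 3.81 ± 0.07), and miR-150 was 18.5-fold lower. miR-146a (log2 -0.03 ± 0.09) and miR-155 (0.22 ± 0.07) were not called. Of the 5 leukocyte-enriched assays 2 were higher and 1 lower, against 4 and 1 with both snoRNA202 and the global mean. Camera gave the leukocyte list an adjusted p of 0.339 (0.508 with an estimated correlation). miR-126-3p was 3.71-fold lower (log2 1.16 with snoRNA202), and miR-143 was 4.82-fold lower (log2 0.78 with snoRNA202). miR-145 was 30.4-fold lower. In the mesenchymal and smooth muscle list 3 of 4 assays were lower, against 1 lower and 2 higher with snoRNA202 and 2 lower with the global mean, with a camera adjusted p of 0.0884 (0.320 with an estimated correlation). miR-27b was 4.29-fold lower, with a log2 change of 0.95 with snoRNA202. miR-16 had a log2 change of -0.76 ± 0.06, with 2.29 with snoRNA202, 0.10 with snoRNA135 and 0.27 with the global mean.

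**Figure D3:**
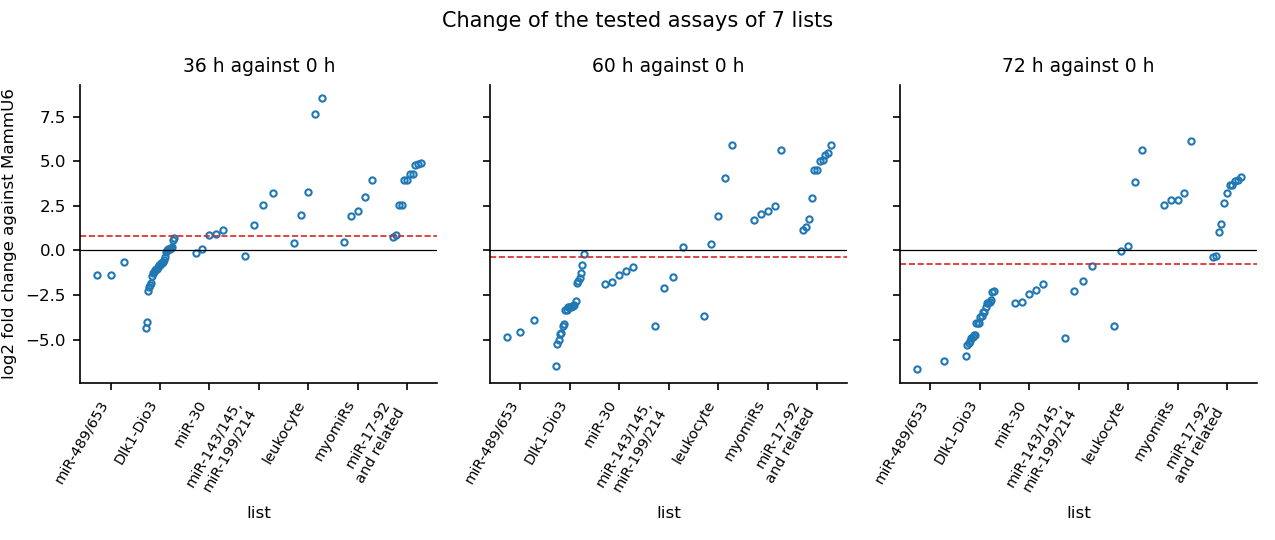
Log2 change against 0 h (vertical axis) of each tested assay of 7 lists (horizontal axis) at 36, 60 and 72 h, with 1 point per assay and the median of all tested assays as a red dashed line. With U6 as normalizer the median Dlk1-Dio3 assay lies below this line at each time, by 1.63 at 36 h (29 assays), 2.77 at 60 h and 3.13 at 72 h (22 assays each), a trend not tested, and with snoRNA202 as normalizer some of them are higher at 36 and 60 h. The line pools both cards, whose medians at 72 h were -1.37 (card A) and -0.28 (card B). The gap within each card was not computed.

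The later groups were compared with each other to follow the course of activation. From 36 to 60 h, miR-182 rose 6.74-fold, miR-31 6.26-fold, miR-31* 6.13-fold, miR-133b 3.13-fold and miR-206 2.95-fold (log2 1.56 ± 0.12). miR-143 fell 25.3-fold, miR-150 16.9-fold, miR-126-3p 16-fold, miR-145 14.9-fold and miR-10a 14.8-fold. miR-223 fell 12.1-fold, miR-451 12.8-fold (log2 -4.28 to -2.92 without 1 of the 60 h arrays), and miR-489 10.9-fold on the mouse assay and 9.19-fold on the rat assay. miR-27b fell 2.73-fold and miR-16 2.25-fold, and with snoRNA202 the log2 change was 0.08 for miR-27b and 0.36 for miR-16. miR-1 fell 2.41-fold on the mouse assay, a direction that turned with snoRNA202 (log2 0.26), and had a log2 change of 0.28 ± 0.08 on the rat assay. The rat assay was called with snoRNA202 (1.81) and the global mean (1.73). miR-133a (log2 0.27 ± 0.07) and miR-21 (-0.69 ± 0.06) were not called, while with snoRNA202 and the global mean miR-133a was called (1.79 and 1.71) and miR-21 was above 0 (0.83 and 0.76). Of 279 tested assays 153 changed, 15 higher and 138 lower, against 94 and 54 with snoRNA202 and 75 and 64 with the global mean. Detected at 60 h alone were 6 assays, including miR-183* (at least 182-fold higher), miR-183 (at least 46.1-fold) and miR-675-3p (at least 10.4-fold), and against their highest 36 h spot miR-879* (6.23-fold) and miR-501-3p (2.69-fold). Detected at 36 h alone were 38, including let-7a (at least 827-fold lower), let-7f (at least 321-fold) and rno-miR-136* (at least 161-fold), and against their highest 60 h spot miR-15a (7.11-fold) and miR-696 (3.69-fold). Of the 6 and the 38, 2 and 10 had some spot of the other group with a Ct below 35. The let-7a assay gave a Ct on only 1 of 3 arrays at 0 h, at 26.9. Its bounds at 60 and 72 h may thus reflect failed reactions.

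The mesenchymal and smooth muscle list was lower at 60 h than at 36 h for 4 of 4 assays (4 over the list alone), in camera with an adjusted p of 0.0428, lost with an estimated correlation (adjusted p = 0.311). Of 6 leukocyte-enriched assays 5 were lower (5 over the list alone), against 4 lower and 1 higher with snoRNA202. Camera gave this list an adjusted p of 0.207 (0.419 with an estimated correlation). The Dlk1-Dio3 list had 18 of 22 assays lower (18 over the list alone), against 13 lower and 1 higher with snoRNA202 and 14 and 1 with the global mean. Its camera call (adjusted p = 0.00369) was lost with an estimated correlation (adjusted p = 0.174). Of 12 tested miR-17-92 assays 2 were higher (2 over the list alone), against 11 with snoRNA202 and 11 with the global mean, and the list lay above the other assays in camera (adjusted p = 6.36e-08), a call lost with an estimated correlation (adjusted p = 0.106).

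From 36 to 72 h, miR-335-3p rose 5.11-fold, rno-miR-351 5.07-fold, miR-206 5.07-fold (log2 2.34 ± 0.12), miR-133b 4.44-fold and miR-31* 3.92-fold. miR-136 fell 43.9-fold, miR-489 38.5-fold (log2 -5.27 ± 0.16; 29.2-fold on the rat assay), miR-146b 37.2-fold and miR-195 29.6-fold, and miR-204 fell by 5.13 on the log2 scale. miR-133a rose 2.42-fold, and the log2 change of miR-31 was 1.72 ± 0.09. miR-126-3p fell 17.3-fold, miR-223 14.3-fold, miR-27b 5.36-fold, miR-16 4.36-fold and miR-21 4.36-fold. With snoRNA202 the log2 changes of miR-16 (0.05), miR-21 (0.05) and miR-27b (-0.25) were not called. miR-1 was not called on the mouse assay (log2 -0.41 ± 0.24) or the rat assay (0.62 ± 0.08). Both were called with snoRNA202 (1.76 and 2.79) and the global mean (1.91 and 2.94), the rat assay also with snoRNA135 (1.27). Of 270 tested assays 198 changed, 11 higher and 187 lower, against 70 and 69 with snoRNA202 and 76 and 68 with the global mean. Detected at 72 h alone were 6, including miR-675-3p (at least 18.9-fold higher), miR-183 (at least 15.2-fold), miR-298 (at least 12.4-fold) and miR-129-3p (at least 6.92-fold), and miR-501-3p, 4.70-fold above its highest 36 h spot. Detected at 36 h alone were 47, including let-7a (at least 1002-fold lower), let-7f (at least 388-fold) and miR-696 (at least 159-fold), and against their highest 72 h spot miR-10b (1379-fold), miR-382 (95.6-fold) and miR-451 (66.2-fold). A spot of the other group had a Ct below 35 for 2 of the 6 and 24 of the 47. The muscle-enriched list, with 3 of 5 assays higher (3 over the list alone, 5 with snoRNA202 or the global mean), lay above the other assays in camera (adjusted p = 2.26e-06), and kept this with an estimated correlation (adjusted p = 0.0352).

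From 60 to 72 h, 2 of 265 tested assays were higher and 95 lower. The increases were miR-503 (2.27-fold, log2 1.18 ± 0.21) and miR-133a (2.01-fold, 1.01 ± 0.07). Without the second 60 h replicate both fell below the minimum fold (log2 0.97 and 0.93), as did miR-133a without the first 72 h replicate (0.97). miR-29b fell 7.77-fold, miR-376b 6.23-fold, miR-106b* 5.38-fold, miR-497 4.91-fold and miR-20a* 4.30-fold. miR-489 fell 3.51-fold on the mouse assay and 3.18-fold on the rat assay, and miR-21 2.70-fold, a call lost with snoRNA135 (log2 -0.90), snoRNA202 (-0.79) and the global mean (-0.56). The mouse miR-489 call was lost with the global mean (log2 -0.94). Not called were miR-206 (log2 0.78 ± 0.12), miR-133b (0.50 ± 0.11), miR-1 (0.86 ± 0.24 on the mouse assay, 0.34 ± 0.08 on the rat assay), miR-31 (-0.92 ± 0.09), miR-27b (-0.97 ± 0.10), miR-16 (-0.95 ± 0.06), miR-126-3p (-0.11 ± 0.05) and miR-223 (-0.24 ± 0.07). With snoRNA135, snoRNA202 and the global mean in that order, miR-133b (1.03, 1.15 and 1.38) and mouse miR-1 (1.39 to 1.73) were called. miR-206 (1.21) and rat miR-1 (1.21) were called with the global mean alone, and miR-126-3p (0.42, 0.53 and 0.76) and miR-223 (0.28, 0.40 and 0.63) were above 0. The split of calls was 8 and 51 with snoRNA135, 9 and 37 with snoRNA202, and 25 and 17 with the global mean. Detected at 72 h alone were 6, including miR-129-3p (at least 4.86-fold higher), miR-339-3p (at least 4.82-fold) and miR-470* (at least 2.04-fold), and against their highest 60 h spot miR-423-5p (1.37-fold) and miR-543 (1.02-fold). Detected at 60 h alone were 11, including miR-879* (at least 6.16-fold lower), and against their highest 72 h spot miR-183* (7.61-fold), miR-215 (5.73-fold), miR-15b* (5.29-fold) and miR-451 (5.19-fold). Most of the 11 were thus not absent at 72 h: 10 had some 72 h spot with a Ct below 35, and 2 of the 6 had such a spot at 60 h. The muscle-enriched list, with 1 of 5 higher (1 over the list alone, 3 with snoRNA202 and 5 with the global mean), again lay above the other assays (adjusted p = 6.11e-06, and 0.0352 with an estimated correlation). The miR-17-92 list had 11 of 12 lower (11 over the list alone), against 3 of 12 with snoRNA202 and 0 with the global mean. Its camera call (adjusted p = 0.00307) was lost with an estimated correlation (adjusted p = 0.311).

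The mean of the 3 later groups was compared with 0 h as an average over activation, which need not hold at each time. miR-31 had a log2 change of 8.75 ± 0.08. miR-182 was higher by 176-fold, miR-142-3p 103-fold, miR-322 72.8-fold, miR-21 51.3-fold, miR-133b 37.5-fold, miR-223 36.0-fold and miR-19a 31.1-fold. miR-133a was 5.41-fold, miR-1 5.32-fold (5.62-fold on the rat assay) and miR-206 3.45-fold higher. miR-485* was 19.8-fold lower, miR-489 19.8-fold (log2 -4.31 ± 0.13; 16.4-fold on the rat assay), miR-667 16.6-fold, miR-127 16.5-fold, miR-495 11.9-fold and miR-337-5p 10.6-fold, and miR-434-3p fell by 3.70 on the log2 scale. miR-16 (log2 0.26 ± 0.05), miR-27b (-0.97 ± 0.08) and miR-126-3p (-0.48 ± 0.04) were not called, while with snoRNA202 miR-16 was at 2.37, miR-27b at 1.14 and miR-126-3p at 1.63. With the global mean miR-27b was called lower. Of 238 tested assays 136 changed, 69 higher and 67 lower, against 88 and 47 with snoRNA135 and 175 and 14 with snoRNA202. Without the 36 h arrays, an alternative chosen after seeing the data, 60 were higher and 100 lower. The Dlk1-Dio3 list had 19 of 20 assays lower (19 over the list alone), against 5 lower and 2 higher with snoRNA202 and 20 lower with the global mean. Camera gave it an adjusted p of 6.36e-08 (0.0318 with an estimated correlation). Muscle-enriched assays were higher for 5 of 5 and miR-17-92 assays for 9 of 11 (5 and 9 over the lists alone, 5 and 11 with snoRNA202). Their camera calls (adjusted p = 0.0193 and 0.000238) were lost with an estimated correlation (adjusted p = 0.202 and 0.215).

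The 3 comparisons against 0 h share the same 0 h arrays. Of 249 assays tested at 36 and 60 h, 63 were higher and 21 lower at both, where independent calls would give 32.6 and 9.14, and 11 changed in opposite directions. Of 239 tested at 60 and 72 h, 48 were higher and 81 lower at both (independent 14.9 and 37.9), and 0 changed in opposite directions. Of 243 tested at 36 and 72 h, 46 were higher and 20 lower at both (independent 24.4 and 11.1), and 20 changed in opposite directions. Across assays, which are not independent replicates, the covariance of the log2 changes was 3.96, 6.04 and 3.68 for these pairs in that order, and simulated unchanged groups against the same 0 h arrays gave 0.0312, 0.0269 and 0.0285. In these simulations at most 0.01 assays per set on average were called in the same direction at both times. They cover the technical spread of the 0 h arrays and not variation between mice. Over 238 assays tested at 36, 60 and 72 h, 44 were higher and 17 lower at each.

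In the authors' deposited table, the median fold change differed from that above mainly on card B at 36 h. The median difference between the deposited and the refitted log2 change was 2.30 there, and 0.004 on card A at 36 h and 0.02 on card B at 60 h. Single assays differed by far more: the deposited log2 change exceeded the refitted one by up to 6.55 on card A and 9.39 on card B at 60 h, with r of 0.949 and 0.842 across assays. The constant subtracted on card B at 36 h exceeded the mean U6 Ct of those arrays by 2.26, a factor of 4.78 in fold. All 66 card B assays without a Ct in any group have a fold change of 2.67 at 36 h in the authors' deposited table. Among the 272 assays tested at 36 h, 191 differed by at least 2-fold in that table, 169 higher and 22 lower. At 60 h they numbered 167 (76 higher, 91 lower), and at day 3.5, which correlated with the 72 h values above (r = 0.944 across card A assays, 0.809 across card B assays), 169 (57 higher, 112 lower). The median difference between the day 3.5 and 72 h log2 changes was 0.005 on card A and 0.02 on card B. It was about as small at 60 h (0.003 and 0.02).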

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

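The regroupings of arrays were planned before the result was seen, and the other tests in this part were chosen after it. Against 0 h, 20 assays were higher at 36 h and lower at 72 h, and 0 the reverse. The count was 1 with the mean of the assays detected on 12 arrays and 6 with snoRNA202. The log2 change from 36 to 72 h was -4.84 for miR-143, -4.34 for miR-185, -4.27 for miR-345-5p and -4.19 for miR-126-5p, which had the largest differences among these assays. Each was singled out because it was called higher than 0 h at 36 h and lower at 72 h. A difference of more than log2 2 between the times follows from that selection, so it was not tested independently.

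Of the assays enriched in other cell types, 4 of 5 leukocyte, 3 of 4 mesenchymal and smooth muscle and both miR-126 assays were called higher at 36 h than at 0 h, while miR-215 was lower, a call lost with snoRNA202 (log2 -0.96). A lower share of muscle stem cells as the only source was checked as a rise of all such assays alike. miR-142-3p and miR-145 moved apart by 8.869 (log2), but this cannot decide the question. The pair was picked as the largest and smallest change of 14 assays, and its 0 h levels differed (mean Ct 33.6 and 18.8). An assay already abundant at 0 h need not rise as much as one near the detection limit. RNA from leukocytes at 36 h stays a candidate source: the median change of the 5 tested leukocyte-enriched assays exceeded that of all assays by 2.44, the mean Ct at 36 h was 24.6 for miR-142-3p and 19.9 for miR-223, but miR-150 did not exceed the median assay, and 5 of the 6 list assays were also detected at 0 h. The labels name no cell sort that would remove leukocytes. A change within the stem cells, a lower share of them and leukocyte RNA are all not excluded. The time after injury is confounded with each of them, and the biological explanation was not tested apart from them.

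The median assay was higher against U6 at 36 h and lower at 72 h than at 0 h. A change of U6 alone would shift every other RNA by 1 amount. For 36 h this is argued against by 2 of 4 control RNAs on card A. At 36 h these shifted opposite to the median assay (0.91) by more than 2 SD, with snoRNA135 at -0.22 and snoRNA202 at -0.88. The drop at 72 h was not tested in this way. There the 4 control RNAs on card A fell as the median assay did (-1.37), by unequal amounts. snoRNA135 was at -0.87, snoRNA202 at -3.05, U87 at -1.50 and Y1 at -0.32. On card B at 72 h, Y1 rose by 0.72 and the other control RNAs fell. Whether U6, the control RNAs or total miRNA changed per cell stays open, since no count of cells or spike-in was used here.

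Some assays had a Ct below 30 in 1 group and a spot position without a Ct on any array of another, 22 in number. An assay in more spots counts even if its other position had a Ct, as miR-696 at 60 h (2 of 6 spots). Single reactions may fail too, though they are not part of this count. In 8 of 237 sets of replicate spots with a Ct in 1 or 2 of 3 arrays, the lowest Ct was below 30. Failure in a whole group cannot be told apart from a loss of the miRNA. Between 36 and 60 h the largest log2 change of the other 6 let-7 assays was -1.56, far from the bounds of let-7a (-9.69) and let-7f (-8.33), but family members need not change alike. The let-7a assay itself had a Ct on only 1 of 3 technical replicates at 0 h. That spot, at Ct 26.9, lay log2 1.55 below the 36 h level, so this assay can fail with its miRNA present. The folds given as bounds are therefore less certain than those of assays detected in both groups.

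For the 6 comparisons of 3 against 3 arrays, 1 of 10 groupings of the arrays, the real one, gave as many changed assays. The real counts were 153, 161, 163, 153, 198 and 97 and the highest other count was 0, but 10 groupings are too few for a share below 0.05. For the later groups together against 0 h, 1 of 100 groupings, the real one, gave as many (136, against 17 for the highest other). The other groupings mix technical replicates of different times, which widens the spread within their groups. A low count was therefore likely in advance, and these counts cannot decide the question. The replicates are technical, so these groupings bear on technical spread alone, and chance differences between mice or cell preparations stay open.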

How the results depend on the processing

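Fits with the deposited constants, with detection by any spot and without the 36 h arrays were chosen after seeing the data. Of 3326 alternative values of the named assays, 3186 kept their direction and side of the threshold, 50 lost and 36 gained a call, 23 moved and 31 reversed. The 3326 include 231 from a repeat of the main U6 fit, the same by construction, and 1514 from leaving out 1 technical replicate. Values no longer testable, as with a detection limit of Ct 32 (200 values against 231), are not counted as lost. Most changed values came with snoRNA202 or the mean of the assays detected on 12 arrays (the global mean), whose construction shifts every assay of an array by 1 amount. Unchanged were 167 of 231 values with snoRNA202 and 181 of 231 with the global mean. With snoRNA202 the following log2 changes reversed. At 60 h against 0 h: miR-126-3p 0.63, miR-27b 1.28, miR-30a 0.66, miR-30d 0.55 and miR-143 0.32. At 72 h against 0 h: miR-126-3p 1.16, miR-126-5p 0.81, miR-27b 0.95, miR-16 2.29, miR-143 0.78, miR-25 2.66, miR-92a 2.75, miR-30a 0.15, miR-30d 0.11, miR-29c 1.84, miR-203 0.079, miR-185 1.30 and miR-345-5p 0.83. From 36 to 60 h: miR-1 0.26, miR-16 0.36 and miR-27b 0.077. From 36 to 72 h: miR-21 0.047, miR-1 1.76 and miR-16 0.046. For the later groups together: miR-27b 1.14 and miR-126-3p 1.63. With the global mean, miR-1 (0.18) and miR-16 (0.28) reversed from 36 to 60 h, and miR-21 (0.20), miR-1 (1.91) and miR-16 (0.20) from 36 to 72 h. The count of assays changed from 60 to 72 h was 59 with snoRNA135, 46 with snoRNA202, 42 with the global mean and 200 with no minimum fold, and 206 for the later groups together with no minimum fold, which admits smaller changes. Other alternatives kept each count within 1.5 times. These counts add both directions, and the split could turn. At 60 h against 0 h it went from 70 higher and 91 lower to 179 and 20 with snoRNA202. Leaving out a replicate gave 143 to 153 at 36 h, 150 to 158 at 60 h and 155 to 164 at 72 h against 0 h. It gave 146 to 153 from 36 to 60 h, 188 to 196 from 36 to 72 h, 92 to 101 from 60 to 72 h, and 128 to 137 for the later groups together. From 60 to 72 h, without the second 60 h replicate, 0 assays were higher and 94 lower. miR-378 at 72 h lost its call without the first 0 h replicate (log2 0.96). From 60 to 72 h, miR-1 gained a call without the third 60 h replicate (1.05), and miR-27b without the second 60 h (-1.02), first 72 h (-1.06) or second 72 h replicate (-1.01). Of 142 list counts, 62 moved with snoRNA202, 55 with the global mean and 30 with snoRNA135. A list count also adds both directions, so a list whose assays turned from lower to higher can count as unmoved. Of 99 list tests, 24 passed with the preset and 6 with an estimated correlation. With a replicate block the counts were 154, 162 and 162 at 36, 60 and 72 h against 0 h, 152 from 36 to 60 h, 1 more than without it from 36 to 72 h, 98 from 60 to 72 h and 135 for the later groups together, but replicate numbers do not pair the arrays: the mean correlation of same-numbered arrays was 0.039 on card A and -0.020 on card B. The deposited fold changes are against day 0 alone and gave no value for the other comparisons. Signals near Ct 35 limit what could be detected.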

Other observations

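The let-7 assays, reported to favour differentiation, were higher for 2 of 6 at 36 h and 1 higher and 5 lower at 72 h, against 4 higher and 0 lower at both times with snoRNA202 and, with the mean of the assays detected on 12 arrays (the global mean), 1 higher and 3 lower at 36 h and 1 higher and 2 lower at 72 h (2 and 6 changed over the list alone; camera adjusted p = 0.766 and 0.308). let-7i rose 19.0-fold at 36 h and was 3.69-fold above 0 h at 72 h, while let-7b fell 9.22-fold and let-7c 9.56-fold at 72 h. miR-30 assays were lower for 4 of 5 at 60 h and 5 of 5 at 72 h, against 3 and 1 higher with snoRNA202 and 3 and 4 lower with the global mean. miR-30a fell 7.46-fold and miR-30d 7.65-fold at 72 h, and the camera call at 60 h (adjusted p = 0.0486) was lost with an estimated correlation (adjusted p = 0.330). Both miR-181 assays were lower at 72 h, miR-181a 8.61-fold and miR-181c 9.84-fold, and not called with snoRNA202. miR-15/16 assays were higher for 3 of 5 at 36 h and lower for 2 of 5 at 72 h, miR-195 by 22.2-fold and miR-497 by 15.4-fold, against 3 higher and 1 lower at 72 h with snoRNA202 and 2 and 2 with the global mean, which left 1 higher at 36 h (adjusted p = 0.165 and 0.820). miR-29 assays were higher for 3 of 3 at 36 h and lower for 1 of 3 at 72 h (3 higher at 72 h with snoRNA202 and 1 with the global mean, which left 2 higher at 36 h; adjusted p = 0.235 and 0.803). Of the miR-23/27/24 assays 3 of 4 were lower at 72 h, miR-23b by a log2 change of -4.75, against 1 lower and 2 higher with snoRNA202 and 2 lower with the global mean (adjusted p = 0.152). miR-100 (12.6-fold) and miR-99a (11.3-fold) were lower at 72 h, 2 of 3 assays, against 1 higher and 0 lower with snoRNA202 (adjusted p = 0.344). Of the reported muscle stem cell regulators, 9 of 19 were higher and 2 lower at 36 h and 4 higher and 11 lower at 72 h, against 17 and 0 at 36 h and 11 and 3 at 72 h with snoRNA202, and 5 and 3 and then 7 and 8 with the global mean (11 and 15 over the list alone; adjusted p = 0.126 and 0.709). From 60 to 72 h their camera call (adjusted p = 0.0269) was lost with an estimated correlation (adjusted p = 0.183).

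Other lists had few tested assays. miR-449a (19.7-fold) and miR-34b-3p were higher at 72 h, 2 of 2 tested assays of the miR-34 family list. Of the X-linked miR-322 cluster list, 2 of 2 tested assays were higher at 36 h, but the call of miR-542-3p was lost with the global mean (log2 0.88). A further 4 were detected at 36 h alone, miR-450a-5p (at least 15.4-fold higher), miR-503 (at least 5.35-fold), miR-542-5p (at least 1.10-fold) and rno-miR-351 (27.3-fold above its highest 0 h spot). From 36 to 72 h its camera call (adjusted p = 0.0193) was lost with an estimated correlation (adjusted p = 0.183). In the Sfmbt2 cluster miR-467a was higher at 36 h (9.79-fold), 1 of 2 tested, against 1 higher and 1 lower with the global mean. The epithelial miR-203 was 7.83-fold lower at 72 h and not called with snoRNA202, while miR-200c and miR-205 were detected at 36 h and not at 0 h. Of 3 liver, kidney and pancreas assays, miR-192 was higher and miR-215 lower at 36 h, and with snoRNA202 2 were higher (adjusted p = 0.787). The call of miR-192 was lost with the global mean (log2 0.02) and that of miR-215 with snoRNA202 (-0.96). No nervous-system assay could be tested against 0 h, and 2 were detected at 36 h alone. No embryonic stem cell cluster assay could be tested, and 1, miR-302a, was detected at 0 h alone.

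A hypothesis written before its result was seen held that both strands of a hairpin, measured on different cards, follow the amount of their shared precursor. Across hairpins, which are not independent replicates, Pearson's r between the log2 changes of both strands was 0.350 at 36 h (28 hairpins), 0.415 at 60 h (24) and 0.497 at 72 h (22). The two-sided permutation p was 0.0671, 0.0441 and 0.0188, and adjusted over the 3 comparisons 0.0671, 0.0661 and 0.0563, above the threshold set. Spearman's rho was 0.401, 0.485 and 0.530, with an adjusted permutation p of 0.0353, 0.0261 and 0.0261. The hypothesis is left undecided: the planned bound counted a p above the threshold against it, but such a p does not show that no relation exists, and the rank correlation passed.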
